A study of Mus musculus with 10 samples.

How the data were processed

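Pooled total RNA of 10 tissues of CD1 mice was measured on a splicing array with exon-body and splice-junction probes, 1 sample per tissue, per the labels. The deposited table holds 21882 probe values per sample, for events numbered between 1 and 4341, with 7 probe kinds for each of 3126 events. The values are treated as a score deposited by the authors, on a compressed scale that never falls below 0. The labels and the table header state neither the base of the scale nor the transformation. Scanner, dyes, background correction, probe sequences and between-array normalization are not given in the sources used here. Column medians between 2.04 and 2.19 differ little. No rows of the table were duplicated, and no sample columns were left unused.

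Each array was centred on its median. A tissue's deviation was its value minus the median of the other 9 tissues. The planned threshold of 4-fold needs a log2 scale. Since the base could not be settled, the planned replacement was used, 4 robust SDs (median absolute deviation times 1.4826) of all deviations. This gave 2.11 units for probes (robust SD 0.527), 2.15 for transcript level (0.537) and 1.61 for the junction index (0.402). Transcript level was the mean of C1 and C2. The junction index was the mean of C1:A and A:C2 minus C1:C2, and the body index was A minus the mean of C1 and C2. Exons were called where the junction index passed its threshold, the body index had the same sign, and the flanking-body probes exceeded the lowest 25% of all values in the tissue and in the median of the others. INT probes entered no index. The roles of the probe kinds were read from the probe suffixes and the labels' mention of exon-body and junction probes.

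With 1 sample per tissue no model was fitted and no p-value was computed for a difference of any probe or exon between tissues. Counts past the threshold describe these arrays, and the number of arrays limits the precision. Similarity between tissues was Pearson's r of values centred over the 10 tissues, with 95% intervals from 200 bootstrap draws of events. Similarity by splicing was compared with similarity by level over 45 tissue pairs by permuting the tissue labels (Mantel test, two-sided, 100000 permutations), with Benjamini-Hochberg adjustment over 14 such correlations. Shared exon calls were set beside the number for independent lists and beside 100 shuffles of the centred indices among exons within each tissue. Similarity across probe sets took C1 in one tissue and C2 in the other for level, and the junction index in one and the body index in the other for splicing.

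The comparisons, the threshold rule, the calling rule and most of the alternative settings were set before the data were examined. The table pairs no gene names with event numbers, so the planned gene lists and the planned averaging per gene were not applied. The rule for named items then allowed at most 2 probes with the highest and 2 with the lowest deviations over all tissues. The same rule was used for exons by splicing index. The alternatives tried were quantile normalization, columns without scaling, the mean as comparator, each tissue left out of the comparator in turn, filters on low values, other thresholds, other indices and rank correlation.

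The calling steps were tested on simulated data with 21882 probes and 3126 events, with 200 seeded changes and a noise SD of 0.296 units per probe. Level changes of 1, 2, 3 and 4 units were recovered in 0%, 22%, 100% and 100% of cases, and splicing changes of the same sizes in 5.56%, 91.9%, 100% and 100%. The simulated noise was far below the threshold, so the simulation does not measure false calls on these arrays. Level changes of 2 units or less and splicing changes of 1 unit were thus largely missed. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.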

Results

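Alternative splicing was profiled in 10 mouse tissues on an array that carried 7 probes for each of 3126 alternative splicing events, 21882 probes in all. For each event, 3 probes lay in exon bodies: a flanking exon on one side of the alternative exon (C1), the alternative exon itself (A) and the flanking exon on the other side (C2). Another 3 crossed splice junctions. The junctions C1:A and A:C2 are made when the alternative exon is included, and C1:C2 when it is skipped. The seventh probe is marked INT, and the sources used here do not say what it measures. The tissues were brain, heart, intestine, kidney, liver, lung, muscle, salivary, spleen and testis, as the labels name them. Each tissue was 1 pooled total RNA sample from mice of the outbred CD1 strain, so there were no replicates, and every difference below describes these 10 samples with no test across animals. Probe values ran from 0 to 8.66 on a compressed, log-like scale whose base is not stated. Differences are therefore given in units of that scale and not as folds. Array medians lay between 2.04 in salivary and 2.19 in brain, and the share of probes at exactly 0 between 0.635% in kidney and 3.33% in salivary. The INT probes were the dimmest kind, with a median of 1.21 over all arrays, against 2.53 for C1 and 2.64 for C2.

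The first comparison asked which transcripts were set apart in each tissue. Testis stood out most, with 1290 probes higher than the median of the other 9 tissues by the fixed threshold of 2.11 units, followed by liver with 754, brain with 643 and kidney with 493. Intestine had 354 high probes, muscle 328, spleen 327 and heart 319, whereas salivary had 183 and lung 128. Low probes were far fewer. They numbered 65 in brain, 55 in testis, 47 in salivary, 44 in heart, 42 in spleen, 20 in liver, 20 in muscle, 12 in intestine, 12 in kidney and 8 in lung. With single tissues left out of the comparator these low counts ranged from 0 to 21 in lung, 6 to 22 in intestine, 23 to 33 in liver, 42 to 82 in brain and 27 to 49 in spleen. In total 4819 calls were high and 325 low, and 93 of the low calls were values at 0. Values stop at 0, and only 49.6% of the probe and tissue combinations had a median of the other tissues high enough for a low call, so the excess of high calls is set in part by this floor. With arrays brought to one distribution by quantile normalization, the order changed. Testis had 838 high probes and brain 698, followed by spleen with 410, muscle with 405 and liver with 401, and lung had 207.

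**Figure D1:**
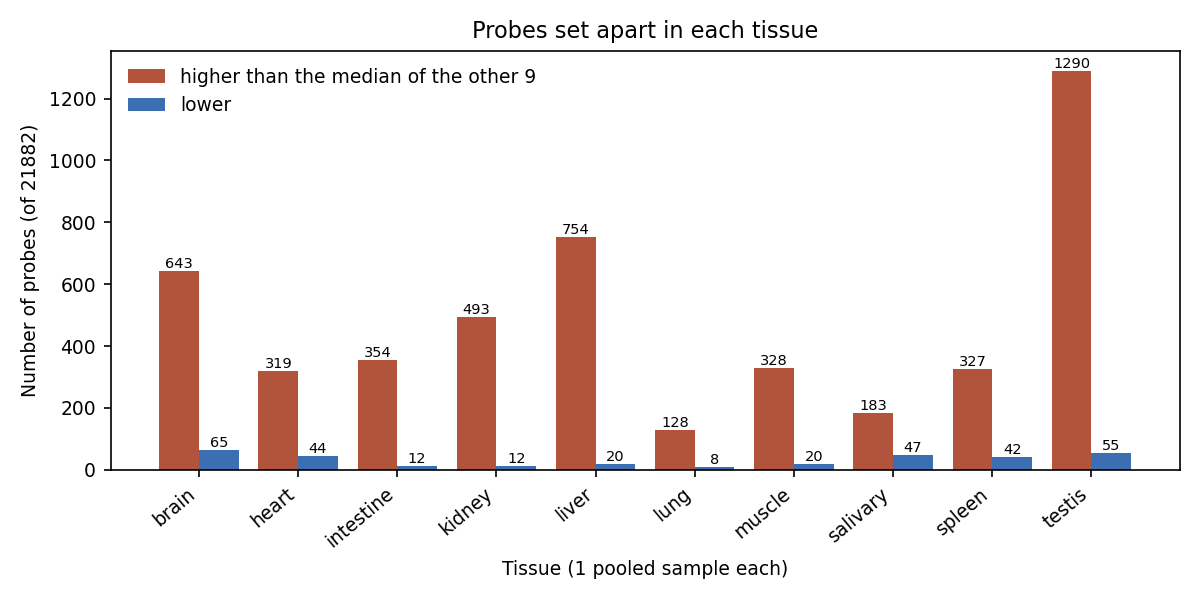
Bars give, for each of the 10 tissues (1 pooled sample each), the number of the 21882 probes at least 2.11 units above (red) or below (blue) the median of the other 9 tissues. Testis has the tallest bar, 1290 high probes, and lung the shortest, 128.

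Of the probes, 2992 were high in 1 tissue, 668 in 2 and 158 in 3 or more. The comparison with the median of the other 9 tissues cannot call a probe that is high in most tissues, so these numbers do not measure how widely transcripts are expressed. The level of a transcript was taken as the mean of its C1 and C2 probes, and by this measure 210 events were high in testis, 119 in liver, 98 in brain, 76 in kidney, 59 in intestine, 40 in heart, 28 in spleen, 25 in salivary, 24 in muscle and 20 in lung. The deviations of C1 and C2 from the other tissues correlated across events at r between 0.62 in salivary and 0.82 in liver. Events are not independent replicates. Of the 763 high calls of C1 probes, 500 came with a high C2 probe of the same event. The 6 exon and junction probes were high together in 69 events in testis, 41 in liver and 18 in kidney.

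The rule for named items gave 2 high probes, both in liver. The A probe of event Ben2069 read 7.96 in liver as deposited. After centring of the arrays it lay 7.76 units above the median of the other tissues, which was 0.273 as deposited. Values this low, like values listed at 0, lie below the median of the INT probes, so deviations from them are not exact sizes and have no order among themselves. The other exon and junction probes of this event were also higher in liver, from 5.02 for C1:C2 to 7.37 for C2. The A probe of event Ben4330 was 7.50 units above the others in liver after centring, where the median of the others was 0.274 as deposited. Its C1 and C2 probes were higher by 5.13 and 5.94. At the low end, the C2 probe of event Ben844 was listed at 0 in brain and in heart, with deviations of -7.68 and -7.58, whereas it read from 6.62 to 8.66 in the remaining tissues. Its A:C2 junction was also lower, with deviations of -4.15 in brain and -4.05 in heart. C1 deviated by -0.17 and -0.07, but values stop at 0, so a probe already low in the other tissues could fall little. The small C1 deviations therefore do not show that the rest of the transcript was unchanged. The C2 probe of event Ben4077 was listed at 0 in kidney, with a deviation of -5.21. All exon and junction probes of Ben4077 were lower in kidney.

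The tissues were next compared with each other across all probes, after each probe was centred on its mean over the 10 tissues. Centring alone would set the correlation of unrelated tissues of equal spread at -0.11. The SD of level deviations ran from 0.575 in lung to 1.15 in testis, so this value is only a rough guide for any pair. Kidney and liver were the most alike, with r = 0.38 (95% bootstrap interval over events 0.34 to 0.42), followed by lung and salivary at 0.34 (0.30 to 0.37). Muscle and spleen followed at 0.21 (0.17 to 0.24), heart and muscle at 0.18 (0.15 to 0.23), and intestine and salivary at 0.14 (0.09 to 0.19). Kidney and muscle were the least alike, at -0.37. On uncentred values, testis had the lowest mean correlation with the other tissues, 0.57, and brain the next lowest, 0.63. These intervals cover the sampling of events only. The order depended on the setting: by Spearman lung and salivary (0.43) stood above kidney and liver (0.39), and intestine and salivary (0.22) above muscle and spleen (0.20) and heart and muscle (0.15). Without the lowest 25% of probes heart and muscle (0.21) stood above muscle and spleen (0.17).

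The pair of muscle and spleen differed from the other close pairs in which probes carried the similarity. By transcript level, from C1 and C2, kidney and liver correlated at 0.42, lung and salivary at 0.32, and heart and muscle at 0.31, but muscle and spleen at -0.00. Between muscle and spleen, the INT probes correlated at 0.66, the highest value of any pair for that kind. Among the 146 probes high in both muscle and spleen, 49 were C1:A junctions, 27 INT, 26 C1:C2, 23 A:C2 and 13 A, whereas 2 were C1 and 6 were C2. The pair correlated at 0.30 in C1:A, 0.24 in C1:C2, 0.22 in A:C2 and 0.12 in A, against 0.03 in C1 and 0.05 in C2. Kidney and liver shared 207 high probes, of which 37 were C1, 47 C2 and 1 INT.

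**Figure D2:**
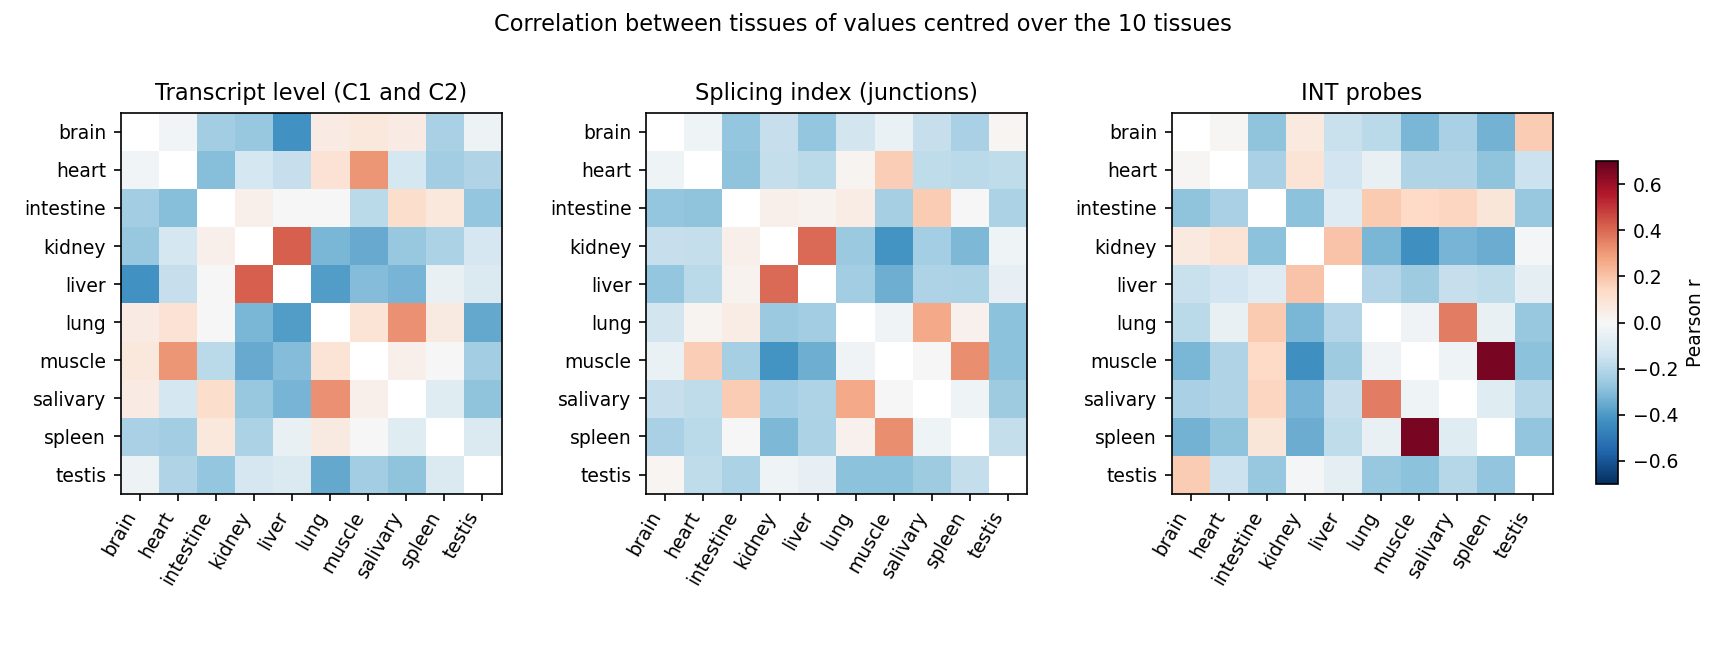
Each panel shows Pearson correlations between the 10 tissues (1 pooled sample each) of values centred over the tissues, for transcript level from C1 and C2 (left), the junction-based splicing index (middle) and INT probes (right). Kidney and liver are alike in level (0.42) and in the index (0.40), while muscle and spleen are alike in INT probes (0.66) and much less in level (-0.00).

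Exon inclusion was then compared between tissues, the purpose the series title states. The splicing index was the mean of the inclusion junctions minus the skipping junction. An exon was called in a tissue when its index lay at least 1.61 units from the median of the other 9 tissues, with the same sign in the body index (A minus the mean of C1 and C2). Testis had the most calls, 34 exons more included and 58 more skipped. Brain followed, with 43 more included and 28 more skipped. After quantile normalization, with the threshold also recomputed, brain had the most, with 40 included and 33 skipped, against 28 and 34 in testis. Heart had 21 included and 33 skipped, kidney 23 and 26, liver 13 and 34, muscle 27 and 14, intestine 6 and 27, spleen 13 and 13, lung 3 and 21, and salivary 7 and 10. Brain and muscle had more included than skipped exons, also after quantile normalization, but which tissues did so depended on the index, filter, threshold and comparator. With A:C2 as the only inclusion junction muscle had 10 of each and kidney 24 included and 18 skipped. At 6 robust SDs brain had 8 included and 10 skipped, and at 2 robust SDs testis had 226 and 164 and kidney 131 and 129. By the body index spleen had 15 and 6 and salivary 18 and 15, and with no filter spleen had 23 and 20. Without brain in the comparator spleen had 16 and 13, and salivary had 11 and 10 without spleen and 10 and 9 without muscle. Over all tissues 190 calls were more included and 264 more skipped, so 41.9% were inclusions. A further filter required the mean of the inclusion junctions, and C1:C2, each to exceed the 95th percentile of the INT probes. Passing in the tissue or in the median of the others was enough. With this filter 63 calls were inclusions and 37 were skips, 63.0% inclusions, with 15 and 4 in heart, 4 and 1 in kidney and 6 and 4 in liver.

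**Figure D3:**
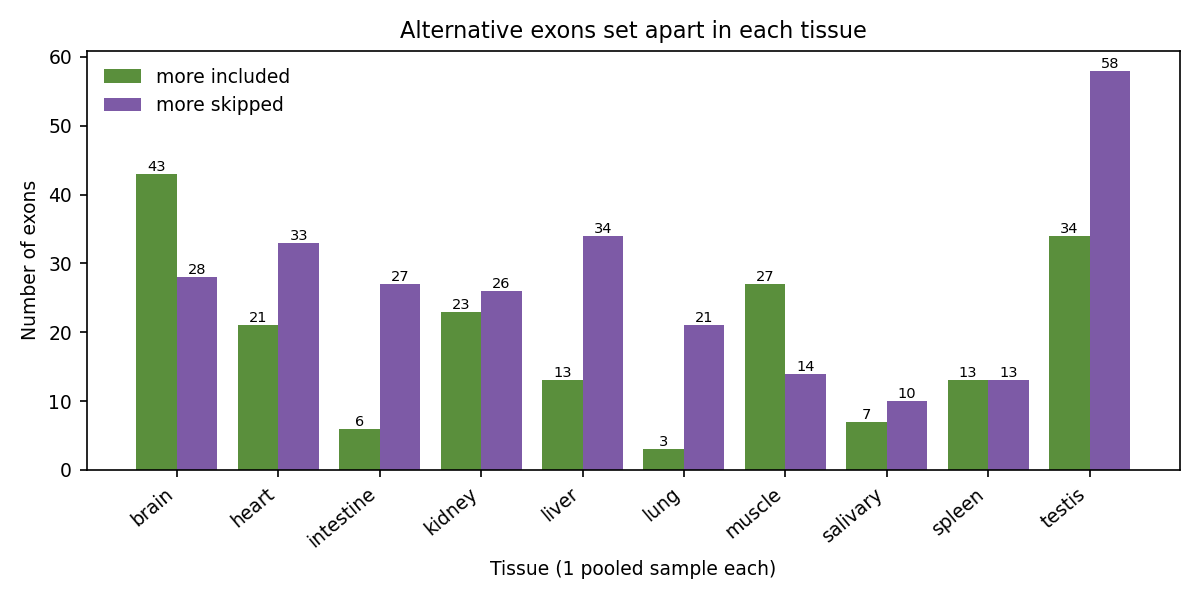
Bars give, for each tissue (1 pooled sample each), the number of alternative exons more included (green) or more skipped (purple) than in the median of the other 9 tissues. Brain (43 and 28) and muscle (27 and 14) have more included than skipped exons, and testis has the most skipped, 58.

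In total 327 of the 2484 testable exons, 13.2%, were called in at least 1 tissue. Of these, 240 were called in 1 tissue, 59 in 2 and 28 in 3 or more, and 30 were more included in one tissue and more skipped in another. The index passed the threshold 528 times, and the body index had the same sign 454 times and the opposite sign 74 times. Heart and muscle shared 14 exons called in the same direction, against 0.456 for independent lists and at most 2 when centred indices were shuffled among exons. The shuffles averaged 0.18 for this pair, below the value for independent lists, so they can understate the sharing reached by chance. Kidney and liver shared 11, muscle and spleen 8, brain and muscle 7, and liver and testis 7. The tissues of a pair are set against largely the same comparator samples, so their calls are not independent.

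Exon calls fell often on transcripts whose level was also called, 105 times against 11.6 for independent calls. In 78 of these the transcript was high and the exon more skipped. There the flanking exons were higher by medians of 2.66 (C1) and 2.84 (C2) and the skipping junction by 2.82, but A by only 0.28, C1:A by 0.47 and A:C2 by 0.33. In 25 the transcript was high and the exon more included, with A higher by a median of 3.75 and C1:C2 by 0.58. Most calls, 163 inclusions and 186 skips, lay on transcripts without a level call. Over all testable exons of a tissue the index deviation correlated with the level deviation at -0.15 to 0.05. High transcripts gave calls in both directions, which cancel in a signed correlation. It therefore does not show that the size of the index deviation was unrelated to level.

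The rule for named items gave 4 exons, and in Ben1029, Ben94 and Ben2456 some junction probes read below the median of the INT probes in most tissues, so these sizes are not exact and set no order among exons. For event Ben1029, inclusion was higher in muscle. There its index was 3.82 units above the other tissues and its body index 3.46 above, while its level deviated by -0.41. The same exon was called more included in heart, by 1.96, and in salivary, by 2.05. In testis, the exon of event Ben2456 was more included by 3.80, with a body index higher by 3.26. This rested on A:C2, higher by 4.74, and on C1:C2, at -1.66, whereas the other inclusion junction, C1:A, was not higher in testis and read only 0.829 there, below the median of the INT probes. Its flanks moved apart, C1 by -1.57 and C2 by 3.15. The exon of event Ben94 was called more skipped in testis, with an index deviation of -4.89 and a body deviation of -4.85. This rested on C1:C2 and the flanks, as no inclusion probe fell. The A:C2 junction was higher by 1.14, at 6.27 in testis against 4.92 to 5.36 elsewhere, and C1:A was higher by 0.68. Its C1:C2 junction read 6.35 in testis and 0.0830 to 1.478 elsewhere. The level of Ben94 was 5.13 units higher in testis, while its A probe was higher by 0.40. In brain the exon of event Ben3726 was called more skipped, with an index deviation of -4.27, a body deviation of -3.38 and a level higher by 3.47. This rested on the flanks and on C1:C2, higher by 4.22, whereas A, C1:A and A:C2 deviated by 0.12, 0.09 and 0.02. In some tissues C2 and C1:C2 read below the median of the INT probes, at 0.39 and 0.20 in spleen, so the size is not exact here either. The exon was also called more skipped in intestine, at -1.81.

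**Figure D4:**
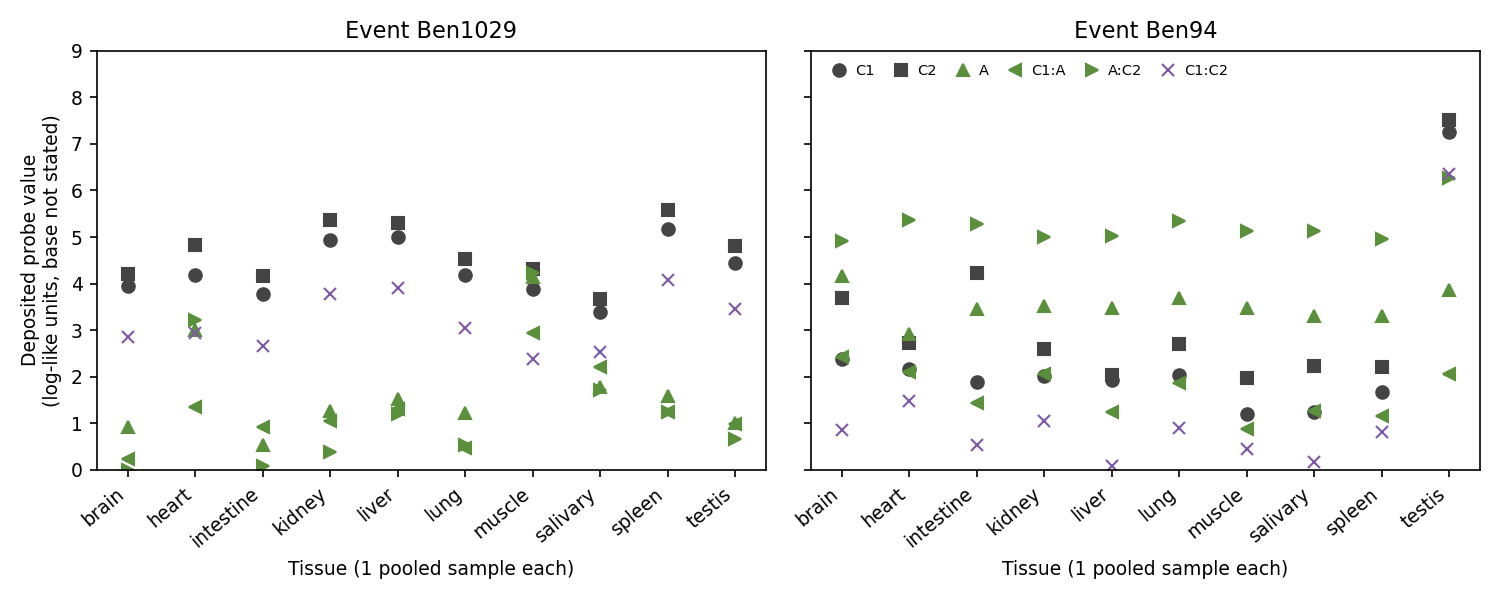
Probe values (log-like units of unstated base) of 6 probes of events Ben1029 (left) and Ben94 (right) in each of the 10 tissues, 1 point per probe and pooled sample. In Ben1029 the A probe reaches 4.13 in muscle with flanks of 3.89 and 4.32, and in Ben94 the flanks rise to 7.26 and 7.51 in testis while A is at 3.86.

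Finally, the similarity of tissues by splicing index was set against their similarity by transcript level. Tissue pairs that were alike in level were alike in the index. Kidney and liver correlated at 0.42 in level and 0.40 in the index, lung and salivary at 0.32 and 0.27, and heart and muscle at 0.31 and 0.17. Muscle and spleen departed from this, with -0.00 in level and 0.33 in the index. Over the 45 tissue pairs, Pearson's r was 0.866 and Spearman's rho 0.864, each with p = 1e-05 (permutation of the 10 tissue labels, two-sided, 100000 permutations), the smallest p they can give. The Benjamini-Hochberg value over the 14 correlations of this kind was 1.75e-05 for each. Similarity by the INT probes, which enter no index, also correlated with similarity by the index (Pearson's r = 0.743, permutation p = 1e-05, the smallest possible, Spearman's rho 0.683) and with similarity by level (0.504, permutation p = 0.00319, adjusted 0.00406). Between splicing across probe sets and the INT probes r was 0.394 (permutation p = 0.0173, adjusted 0.0173). Without liver and testis, the tissues farthest from the median in level similarity, r was 0.789 (permutation p = 5e-05). With level and splicing each taken from different probes in the members of a pair, r was 0.897 (permutation p = 1e-05, again the smallest possible). The body index holds C1 and C2, so level and splicing still shared probes there. Muscle and spleen then stood at -0.05 in level and -0.00 in splicing.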

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

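The thresholds of 2 and 6 robust SDs, the filter on junction probes, A:C2 as the only inclusion junction, different probe sets in the members of a pair and leaving out muscle and spleen were chosen after seeing the data. Alternatives planned in folds, on a floor before the logarithm, per gene and for gene lists were not run, because the scale has no stated base and the table names no genes. No paired analysis was possible because each tissue has 1 sample and no result comes from a replicated test. The correlation between similarity by splicing and by level kept its direction and its side of the threshold in the alternatives run. It was 0.831 with the body index (0.826 by Spearman), 0.864 by Spearman with the junction index and 0.897 across probe sets. It was 0.936 without muscle and spleen and 0.789 without liver and testis. The body index, also used across probe sets, holds C1 and C2 as level does, so those values share probes with level by construction. Columns as deposited, tried for the counts of high and low probes, moved none of these by over 1.5 times, and restricting probes to a range above 1 unit moved none of the correlations beyond its interval. Low signal is one limit: events with both flanks above the 95th percentile of the INT probes numbered from 255 in salivary to 1070 in liver. The causes of the shifts below were not tested, except that a lower or higher threshold and a stricter filter change counts by construction.

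Under quantile normalization high probes numbered 401 in liver, 207 in lung and 838 in testis, and skipped exons 14 in liver, 22 in muscle and 34 in testis. The correlations were -0.0448 for brain and lung, 0.0184 for brain and testis and 0.30 for lung and salivary. Under Spearman they were 0.0451 for brain and lung, 0.0373 for brain and testis, 0.15 for heart and muscle, 0.22 for intestine and salivary and 0.43 for lung and salivary. Without the lowest 25% of probes, 415 probes were high in brain, and the correlation was 0.0459 for brain and lung and 0.44 for kidney and liver. Against the mean of the other tissues, 22 probes were low in kidney and 31 in liver. With the body index as the calling index, included exons numbered 3 in intestine, 9 in lung and 18 in salivary, and skipped exons 6 in spleen. With no filter, skipped exons numbered 48 in brain and 20 in spleen, and included exons 23 in spleen. With A:C2 as the only inclusion junction, skipped exons numbered 21 in heart, 11 in lung and 6 in spleen, and included exons 10 in muscle, 12 in salivary and 5 in spleen.

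With each tissue left out of the comparator in turn, low probes ranged from 42 to 82 in brain, 6 to 22 in intestine, 23 to 33 in liver, 0 to 21 in lung and 27 to 49 in spleen, and included exons from 2 to 6 in lung and 5 to 11 in salivary. Low probes in brain fell to 42 without liver. In intestine they were 6 without heart, 7 without muscle, 19 without salivary, 20 without liver and 22 without spleen. In liver they were 33 without kidney and 31 without testis, and in spleen 27 without kidney. In lung they were 0 without liver, 3 without testis, 4 without kidney, 17 without spleen, 18 without intestine, 20 without salivary and 21 without brain. Included exons in lung were 6 without muscle, 6 without salivary and 5 without spleen, and in salivary 11 without spleen.

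The filter on junction probes asked for junctions above the 95th percentile of the INT probes in the tissue or in the median of the others. Included and skipped exons were then 14 and 4 in brain, 2 and 3 in intestine, 4 and 1 in kidney, 6 and 4 in liver, 0 and 2 in lung, 10 and 3 in muscle, 0 and 2 in salivary, 1 and 2 in spleen and 11 and 12 in testis, with 4 skipped in heart and 63 and 37 over all tissues.

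At 2 robust SDs, high and low probes were 2083 and 890 in brain, 1881 and 701 in heart, 1303 and 437 in intestine, 2518 and 418 in kidney, 2694 and 662 in liver, 823 and 451 in lung, 1147 and 577 in muscle, 899 and 758 in salivary, 1258 and 779 in spleen and 3428 and 1215 in testis, 18034 and 6888 in total, or 72.4% high against 93.7%. Included and skipped exons were then 202 and 141 in brain, 99 and 150 in heart, 52 and 104 in intestine, 131 and 129 in kidney, 139 and 142 in liver, 43 and 110 in lung, 112 and 87 in muscle, 73 and 88 in salivary, 78 and 90 in spleen and 226 and 164 in testis, 1155 and 1205 in total.

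At 6 robust SDs, high and low probes were 175 and 6 in brain, 80 and 8 in heart, 114 and 0 in intestine, 153 and 6 in kidney, 252 and 5 in liver, 18 and 0 in lung, 97 and 2 in muscle, 51 and 20 in salivary, 80 and 0 in spleen and 584 and 1 in testis, 1604 and 48 in total. Included and skipped exons were 8 and 10 in brain, 5 and 7 in heart, 2 and 8 in intestine, 6 and 6 in kidney, 4 and 9 in liver, 0 and 2 in lung, 8 and 6 in muscle, 1 and 4 in salivary, 1 and 3 in spleen and 8 and 24 in testis, 43 and 79 in total.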

Other observations

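The tests on muscle and spleen of level and of shared inclusion across probe sets were chosen only after the results were seen.

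The INT probes, which entered no splicing index, were high in 149 cases, 32 of them in testis, 31 in spleen and 27 in muscle. Of the 699 high calls of level, counted over events and tissues, 17 came with a high INT probe in the same tissue. This is a small share but larger than that over all events and tissues. INT and level deviations correlated across events at 0.124 in muscle to 0.265 in intestine. In muscle and spleen 49 INT probes lay at least 1 unit above the other tissues in both, by medians of 2.25 and 2.36, and the values in muscle and spleen differed by a median of 0.11, while the level of those events deviated by a median of only -0.03.

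Event Ben844 had its C2 probe at 0 in brain and heart and at 6.62 or more elsewhere, while C1, A and the C1:A and C1:C2 junctions of the event deviated by less than 1 unit in brain and in heart. All 6 exon and junction probes were low together in 3 events in salivary and 1 in kidney.

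Muscle and spleen resembled each other in the splicing index (0.33) and in INT probes (0.66), and far less in level (-0.00). Centring would set unrelated tissues of equal spread at -0.11, but the spread differed between tissues, so values for unrelated tissues are rough guides. With C1 in one tissue set against C2 in the other, level correlated at -0.0465 (-0.0806 to -0.0129). Unrelated tissues of equal spread would give -0.0808, just outside this interval, and kidney and liver gave 0.34. Level in the flanking exons was thus little shared. INT and level deviations correlated at only 0.124 in muscle and 0.186 in spleen, so this test cannot show whether shared transcripts lay behind the INT similarity. With the junction index in one tissue set against the body index in the other, splicing correlated at -0.00139 (-0.0343 to 0.0312). Unrelated tissues of equal spread would give -0.0364, also just outside the interval. Shared inclusion changes as the whole source would give 0.107, the junction correlation times the agreement of the 2 indices within a tissue. This product is a rough guide: heart and muscle gave 0.166 where it was 0.059, and lung and salivary 0.090 where it was 0.105. The value near 0 argues against shared inclusion changes as the whole source of the likeness in the index. In 100 events the deviation of C1:A from the other tissues exceeded that of the level by at least 1 unit in both muscle and spleen. The median excess over the level deviation was 2.03 for C1:A. It was 0.11 for A:C2 and 0.12 for A, a ratio of 0.0555, against ratios from 0.30 to 0.53 in the other close pairs. Signal of single probes that the muscle and spleen arrays share may thus account for the likeness in C1:A. The other junction kinds were not checked this way. What those arrays had in common is not stated, and a difference in how they were made or cleaned stays untested.

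Testis had the most high probes. A stretched scale of the testis array is argued against by a slope of 0.905 (0.869 to 0.942) of its C1 minus C2 differences on those of the other tissues in 1438 events of steady level, where the other tissues gave 0.761 to 1.15. A wider spread left by the authors' scaling may still contribute: after quantile normalization the testis count of 838 was 1.201 times the brain count of 698, with an interval of 0.997 to 1.44 that includes no excess. A larger set of transcripts used in testis, a difference between tissues that the design names, stays open and was not tested apart from this.

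Exon calls were enriched on transcripts with a called level, and tissues alike in level were alike in the index, although most calls lay on other transcripts. An index set between a tissue with the transcript and tissues nearly without it could give this. With both flanks above the 95th percentile of the INT probes in the tissue and the others, 11 exon and tissue combinations were called on both. Independent calls would give 2.29, so this is 4.80 times (2.40 to 8.59), where all testable combinations gave 9.08 times. The interval treats the combinations as independent, and it leaves the test undecided between the bounds set in advance. Compression of junction signal as level changes could act too. Splicing similarity was therefore taken from the 988 events of steadiest level and level similarity from the other 1974. The correlation over tissue pairs was 0.674 (0.586 to 0.724), against 0.866 before. The relation was thus also seen with splicing from the events that varied least in level. Level can still change in those events, and the interval reaches below the 0.6 set in advance, so the test leaves compression undecided. Inclusion that differs between related tissues less than between unrelated ones, as the design's tissues allow, stays open. Similarity by the INT probes, which enter no index, also correlated with similarity by the index (0.743) and by level (0.504). Whether signal shared between arrays adds to the relation was not tested.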
